A study of Mus musculus with 10 samples.

How the data were processed

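H3K27me3 and input libraries of 5 sorted mouse embryo populations were sequenced as single reads on the SOLiD 4 platform, per the labels' protocols. Chromatin came from pools of cells of many embryos, taken on more than 1 date, and was precipitated with a low-cell-number kit and a Millipore antibody. The deposited read files list aligned positions of 38 bp with strand, and their score column holds 0 for every read. The aligner, its filters and the genome build are not given in the sources used here. The deposited lists of enriched regions give a score per region, which is the authors' own value, and per the file headers they hold regions called at a cutoff of 45. The caller is not given in the sources used here. Scores were used only to rank regions within a list.

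The build was settled from the reads: read ends ran past the end of 5 chromosomes of mm9, 8 of mm10 and 11 of mm7, and of 0 chromosomes of mm8. Lengths and bands of mm8 came with circlize 0.4.16 for R 4.3.3. The gene table at hand was of assembly GRCm38.p6, so no gene was placed on these coordinates. The promoter windows and gene lists planned before the data were examined could for this reason not be used, and the stated fallback was taken, namely 10 kb bins and the deposited regions as units.

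Reads were reduced to 1 per position and strand, moved 75 bp from their 5' end and counted in 10 kb bins of the autosomes and X with Python 3.11.15, numpy 2.4.6, pandas 2.3.3, pyarrow 21.0.0 and scipy 1.17.1. Duplicates made up 16.2% (liver input) to 49.1% (endocrine H3K27me3) of reads. Bins with at least 20 input reads over the 5 inputs were tested, which kept 254986 of 262814. Input was scaled to each H3K27me3 library by the ratio of reads in bins at or below the median of summed reads, which was 0.492 in nonendoderm, 0.264 in endoderm, 0.278 in liver, 0.233 in pancreas and 0.451 in endocrine cells. Log2 enrichment was computed with a pseudocount of 0.5 RPM. A bin was marked when log2 enrichment was 1 or more and the exact 95% Poisson interval of its H3K27me3 reads lay above the scaled input, whose own counting error was not included. Folds of named regions are H3K27me3 reads over scaled input reads without pseudocount, with exact conditional (Clopper-Pearson) 95% intervals for the reads, on background scaling and before quantile normalization.

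For comparisons, log2 enrichment was quantile normalized over the 5 populations, which removes overall differences in yield and with them any true overall difference in the amount of the mark. A bin was called different when the values were 1 or more apart, the higher was 1 or more, and the 95% interval of the difference over 200 Poisson redraws of all counts excluded 0. A count of 0 is always redrawn as 0, so the interval leaves out the counting error of such a count. With 1 library per group no test between conditions was possible and no p-value is given. To see what counting noise alone gives, 5 sets of libraries were simulated in which each bin had the same rank of enrichment in all populations, taken from the mean of the normalized values, which itself holds some noise. The simulated inputs shared the profile of the pooled inputs, and bins were drawn independently. Local differences between the real inputs were thus not part of this noise. These simulations were added after seeing the data, while the calls on deposited regions were part of the stated fallback. The 5 comparisons share libraries and are not independent. In tests on simulated data with 200 bins of 4-fold or higher mean enrichment lowered in the first population of a comparison, 95% of the 100 bins lowered 4-fold and 27% of those lowered 2-fold were recovered for endocrine against pancreas, and 76% and 31% for liver against endoderm, among 254986 bins.

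Because single bins were called in large numbers from noise alone, blocks of 3 or more adjacent bins called the same way were added after seeing the data. The rule fixed before the data were examined names the 5 bins of 10 kb with the largest difference each way. Blocks were ranked by mean difference, and those named are among the 5 largest each way, except the block on chromosome 6 from 42510001 to 42540000, which is named for its opposite direction. These choices, and that of the deposited regions named, were made after seeing the data. All named blocks had the same direction with background scaling alone. The same calls were made on the 8736 deposited regions, of which 5325 had 20 or more input reads. Overlap of lists was counted from 1 bp. Correlations between populations were divided by the square root of the product of split-half reliabilities over 20 random splits of the reads. Figures were drawn with matplotlib 3.10.9.

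The alternatives planned were all reads with duplicates, background scaling without quantile normalization (scaling to total reads for marked bins), the 5 inputs pooled, a pseudocount of 1 RPM, all libraries thinned to the smallest, no filter on input reads, and a threshold of 1.5-fold. For the lists they were regions of 2 kb or wider, the scores at or above the median, and a larger overlap. Leaving out bins whose pooled input exceeded 3 times the median was added after seeing the data. Reads on chromosomes Y and M were left out of all comparisons.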

Results

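Trimethylation of lysine 27 of histone H3 (H3K27me3), the repressive mark set by Polycomb repressive complex PRC2 through its enzyme EZH2, was profiled by chromatin immunoprecipitation and sequencing in 5 cell populations sorted from mouse embryos. ENDM1-positive cells of embryonic day E8.25 were definitive endoderm, and the ENDM1-negative cells of the same stage are called nonendoderm. At E10.5, Liv2-positive, Pdx1-negative cells were immature hepatocytes (liver below) and Pdx1-positive, Liv2-negative cells were pancreatic progenitors (pancreas below). Ngn3-positive cells were endocrine progenitors of the pancreas (endocrine below). Their labels conflict on age, with E14.5 as developmental stage and E10.5 in the source name. The stage field was followed, and the age of these cells is not settled here. The populations follow the path from endoderm to its hepatic and pancreatic branches and on to endocrine commitment, and the comparisons ask where the mark differed at each step. Liver and pancreas against endoderm, and endocrine cells against pancreas by the stage field, also differ in embryonic age. In these comparisons lineage, age and sort marker cannot be told apart. Each population gave 1 H3K27me3 library and 1 input library, 10 libraries in all, from 50000 to 100000 cells. There were no replicates, so every interval given covers counting error only, except a bootstrap interval over blocks in the liver test near the end. No value measures the spread between embryos or sorts.

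The H3K27me3 libraries held 8214956 aligned reads in nonendoderm, 4317652 in endoderm, 3716583 in liver, 4804998 in pancreas and 11135595 in endocrine cells. After removal of reads at the same position and strand, 4905214, 3100527, 2377918, 2851254 and 5667097 reads on the autosomes and X were used, in the same order. The inputs gave 6314140 (liver) to 9765397 (pancreas) such reads. Depth limits what single bins can show: the median 10 kb bin held 7 H3K27me3 reads in liver and 16 in endocrine cells. All positions are on mouse build mm8, for which no gene annotation was used here, so regions are named by coordinates and chromosome band.

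H3K27me3 was found over many bins in every population. Of 254986 bins of 10 kb, 41670 (16.3%) were marked in nonendoderm, meaning that H3K27me3 was at least 2-fold over the scaled input and above it by more than the counting error of the H3K27me3 reads, with the input taken as exact. The number was 41503 (16.3%) in endoderm, 37331 (14.6%) in liver, 35062 (13.8%) in pancreas and 61985 (24.3%) in endocrine cells. A core of 13147 bins (131 Mb) was marked in all 5 populations, and 168704 bins were marked in none. These levels depend on the scaling and on the input: with the 5 inputs pooled, the marked bins numbered 21899, 22680, 19620, 19457 and 33857 in the same order. With scaling to total reads the endocrine number was 24357, against 25070 in endoderm, so the endocrine excess was not kept.

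The 3 longest stretches marked in all 5 populations lay in G-light bands, and the next longest, of 200 kb, in a darker one (19qC3). The longest spanned 230 kb on chromosome 11 from 95960001 to 96190000 (band 11qD), with enrichment of 9.56-fold or more in each population. Stretches of 220 kb each lay on chromosome 17 from 35640001 to 35860000 (band 17qB1) and on chromosome 2 from 164740001 to 164960000 (band 2qH3). Of 7902 stretches in all, 5403 were a single bin of 10 kb, 344 reached 50 kb and 55 reached 100 kb.

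Enriched regions listed by the authors were used for 3 of the populations, and no list for nonendoderm or liver was used here. The endoderm list held 4890 regions over 11.4 Mb, the pancreas list 5678 over 13.2 Mb and the endocrine list 8348 over 17.7 Mb. The lists were largely nested. Of the endoderm regions, 82.7% were on the pancreas list and 93.8% on the endocrine list, and 95.1% of the pancreas regions were on the endocrine list. All regions shared by a pair of lists had identical coordinates in both, so the lists appear drawn from a common set of regions, and overlap by random placement is no measure for them. In the opposite direction, 64.7% of the endocrine regions were on the pancreas list. All 3 lists shared 3851 of 8736 regions (44.1%), a share that was 61.2% among regions of 2 kb or wider and 26.96% when each list was limited to scores at or above its own median.

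Absence from a list did not mean absence of the mark. The 2211 regions listed only for endocrine cells had 19.5-fold (95% interval 19.1 to 19.99) enrichment there, and the summed reads still gave 4.09-fold (95% interval 3.99 to 4.195) in pancreas and 4.46-fold in endoderm. Of these regions 60.3% reached 2-fold in pancreas and 63.3% in endoderm. In nonendoderm and liver, for which no list was used, the same regions stood at 4.30-fold and 5.73-fold. Because overall enrichment differed between libraries, each class was also set against the regions on all 3 lists, which had 14.0-fold enrichment in endoderm, 16.3-fold in pancreas and 32.5-fold in endocrine cells. On that scale the endocrine-only regions reached 60.1% of the shared level in endocrine cells, 25.1% in pancreas and 31.9% in endoderm.

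The following values in endoderm, pancreas and endocrine cells are conditioned on list membership, as are those of the endocrine-only regions, since the lists come from the same libraries, and only nonendoderm and liver are free of this selection. The 192 regions listed for endoderm and pancreas but not for endocrine cells had 14.0-fold (95% interval 13.1 to 15.04) enrichment in endoderm and 13.01-fold (95% interval 12.2 to 13.9) in pancreas, against 5.02-fold (95% interval 4.66 to 5.42) in endocrine cells. This was 15.5% of the shared level in endocrine cells, compared with 79.9% in pancreas. Liver, at 27.5-fold, and nonendoderm, at 13.5-fold, kept these regions near their own shared level (99.2% and 111%). The 87 regions listed for pancreas alone reached 47.4% of the shared level in pancreas, 28.6% in endoderm, 16.5% in endocrine cells and 68.0% in liver. At equal depth (2376466 H3K27me3 reads per library), 8390 of the 8736 regions were marked in endocrine cells, 7341 in pancreas, 7178 in endoderm, 7021 in liver and 6670 in nonendoderm.

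**Figure D1:**
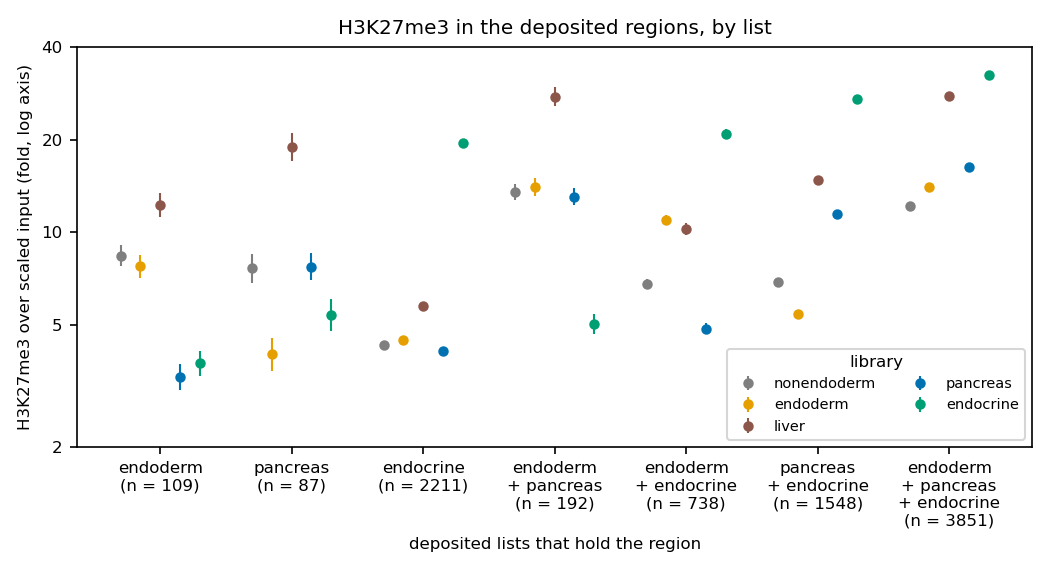
Enrichment of H3K27me3 over scaled input (fold, log axis) in the deposited regions, grouped on the x axis by the lists that hold them, with 1 point per library and 95% counting intervals as bars. Regions listed for endoderm and pancreas but not endocrine cells stood at 5.02-fold in endocrine cells against 32.5-fold for regions on all 3 lists.

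Over the 7967 tested bins that touch a deposited region, log2 enrichment was correlated between populations and corrected for counting noise by split reads. Endocrine cells resembled pancreatic progenitors most (Pearson r = 0.831) and the other three less (0.7003 to 0.709). Liver correlated best with nonendoderm (r = 0.912), then with pancreas (0.891), and least, among the other E8.25 and E10.5 populations, with endoderm (0.777). Endoderm stood at 0.865 with nonendoderm and 0.862 with pancreas. The split-half reliability of the libraries was 0.764 to 0.854. These correlations run across bins, which are not independent replicates, and describe these libraries only. The bins were chosen through the endoderm, pancreas and endocrine lists, without nonendoderm or liver, so the choice may act unequally on the pairs ranked.

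The first comparison asked which domains set definitive endoderm apart from the rest of the embryo at E8.25. Among blocks lower in endoderm the first-ranked lay on chromosome 2 from 147710001 to 147750000 (band 2qG2), where H3K27me3 was 6.93-fold (95% interval 5.73 to 8.42) over input in nonendoderm and 1.14-fold (95% interval 0.786 to 1.62) in endoderm. The mark was also low in pancreas (1.249-fold) and endocrine cells (1.29-fold) but reached 19.6-fold in liver. A similar profile was seen on chromosome 11 from 83650001 to 83680000 (band 11qC), with 5.87-fold in nonendoderm, 1.08-fold in endoderm and 8.78-fold in liver. Folds at blocks, here and below, were not set against each library's level in the regions on all 3 lists. That level was 12.1-fold in nonendoderm, 14.0-fold in endoderm and 16.3-fold in pancreas, but 27.7-fold in liver and 32.5-fold in endocrine cells. Folds in liver and endocrine cells thus run high, and liver cannot be ranked above nonendoderm from them. Lower endoderm values were likewise found on chromosome 7 from 140930001 to 140960000 (band 7qF5), at 1.92-fold against 6.70-fold, and on chromosome 16 from 29960001 to 30000000 (band 16qB2), at 0.792-fold against 3.12-fold. On the opposite side, chromosome 2 from 26350001 to 26390000 (band 2qA3) stood at 8.39-fold (95% interval 6.75 to 10.48) in endoderm and 2.22-fold (95% interval 1.74 to 2.85) in nonendoderm, with 10.4-fold in pancreas and 2.51-fold in liver. Endoderm was also higher on chromosome 15 from 79560001 to 79590000 (band 15qE1), with 7.27-fold in endoderm and 1.79-fold in nonendoderm. H3K27me3 reads there numbered 117 in endoderm and 80 in nonendoderm, and input reads 61 and 91, although the endoderm input was the deeper. Part of this contrast thus came from the inputs, whose differences enter every fold. On chromosome 11 from 119040001 to 119080000 (band 11qE2), endoderm had 8.47-fold and nonendoderm 2.66-fold.

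In all, 43 blocks of 3 or more adjacent bins (1.39 Mb) were higher in endoderm and 54 (1.79 Mb) were lower, against at most 2 each way in 5 simulations in which the populations differed by counting noise alone. The simulations, here and for the other comparisons, gave all inputs a common profile and do not cover local differences between the real inputs. With the 5 inputs pooled, the blocks numbered 24 higher and 37 lower. With background scaling in place of quantile normalization the blocks numbered 59 higher and 30 lower, which turned the balance. It also turned when all libraries were thinned to equal depth, with 57 higher and 30 lower. Single bins called higher and lower numbered 4791 and 5224, against 2625 and 2923 on average in the simulations of counting noise. Among 5325 deposited regions with enough input reads, 308 were higher and 351 lower, against 141 and 169 from counting noise, and background scaling turned this to 339 and 305. The 5 single bins with the largest difference in favour of endoderm over nonendoderm began at 79610001 on chromosome 16, 139530001 on chromosome 7, 114740001 on chromosome X, 67420001 on chromosome 12 and 103760001 on chromosome 14, with log2 differences of 2.85 to 3.41. The 5 on the opposite side began at 96890001 on chromosome 16, 48580001 on chromosome 9, 85060001 on chromosome 3, 137500001 on chromosome 1 and 4480001 on chromosome 1, with log2 differences of -3.31 to -4.19. In 4 of the former and 3 of the latter, the library with fewer H3K27me3 reads held under 10. Where a library held 0 reads in a bin, the size of the difference depends on the pseudocount, and its interval is too narrow. With all reads or with pooled inputs, the single-bin counts of all 5 comparisons moved by more than 1.5 times.

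**Figure D2:**
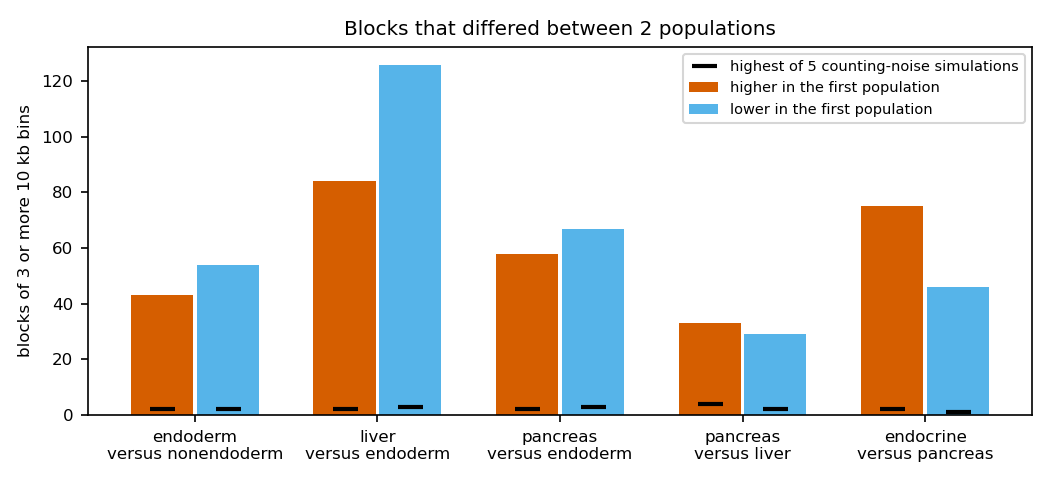
Number of blocks of 3 or more adjacent 10 kb bins (y axis) called higher or lower in the first population of each comparison (x axis), with black marks at the highest number in 5 simulations of counting noise. All bars, from 29 to 126, stand above the marks, which reach at most 4. The simulations do not include local differences between the inputs.

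After quantile normalization, liver against endoderm had the most differing blocks of the 5 comparisons, while with background scaling alone endocrine cells against pancreas had the most. The liver library had 26.7-fold (95% interval 20.7 to 35.0) enrichment on chromosome 2 from 147720001 to 147750000 (band 2qG2), where endoderm had 1.36-fold (95% interval 0.889 to 2.03). This block lay within the chromosome 2 domain that was lower in endoderm than in nonendoderm, and nonendoderm had 7.94-fold there. Cells like those of the nonendoderm library in the liver sort, or a swap of these libraries, were not excluded, as given under other observations. This limit holds for every comparison with liver. On chromosome 1 from 4470001 to 4500000 (band 1qA1), liver had 11.02-fold (95% interval 8.46 to 14.501) and endoderm 0.666-fold (95% interval 0.408 to 1.04), with 3.12-fold in nonendoderm, 3.07-fold in pancreas and 8.73-fold in endocrine cells, so that endoderm had the lowest value of the 5. Higher liver values were also found on chromosome 10 from 44130001 to 44170000 (band 10qB2), with 7.01-fold against 0.840-fold, and chromosome 9 from 118310001 to 118340000 (band 9qF3), with 23.8-fold against 3.50-fold. In the other direction, chromosome 11 from 94740001 to 94770000 (band 11qD) had 11.7-fold (95% interval 8.75 to 15.8) in endoderm and 2.44-fold (95% interval 1.70 to 3.48) in liver, chromosome 17 from 27860001 to 27890000 (band 17qA3.3) had 11.9-fold and 2.80-fold, and chromosome 12 from 109840001 to 109880000 (band 12qF1) had 7.99-fold and 1.71-fold. Input reads at the chromosome 11 block numbered 63 in endoderm and 81 in liver, although the endoderm input was the deeper. The inputs thus added to that contrast.

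Blocks higher in liver numbered 84 (2.95 Mb) and blocks lower in liver 126 (4.31 Mb), with at most 3 from counting noise. Background scaling gave 148 and 146, a share of 50.3% higher in place of 40%, and equal depth gave 81 higher and 75 lower, so the excess of lower blocks was not kept. Single bins numbered 5631 higher and 6402 lower, against 2758 and 3170 from counting noise. The deposited regions gave 508 higher and 463 lower, and 1837 and 180 with background scaling. The 5 single bins with the largest difference in favour of liver over endoderm began at 147730001 on chromosome 2, 77110001 on chromosome 5, 4480001 on chromosome 1, 22320001 on chromosome X and 105080001 on chromosome 5, with log2 differences of 3.72 to 4.04. The 5 on the opposite side began at 100660001 on chromosome 12, 93580001 on chromosome 11, 83260001 on chromosome 6, 51010001 on chromosome 11 and 54970001 on chromosome 13, with log2 differences of -3.25 to -3.79. In 3 of the former and 5 of the latter, the library with fewer H3K27me3 reads held under 10. The region that ranked first among the deposited regions, on chromosome 1 from 4486161 to 4488216 (band 1qA1), lay inside the chromosome 1 block and had 100 reads in liver and 6 in endoderm.

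Pancreatic progenitors against endoderm followed the second branch. The mark was higher in pancreas on chromosome 10 from 66300001 to 66330000 (band 10qB5.1), at 5.63-fold (95% interval 4.43 to 7.16) against 1.24-fold (95% interval 0.843 to 1.80) in endoderm. Higher pancreas values were also found on chromosome 9 from 118300001 to 118340000 (band 9qF3) (10.8-fold against 2.96-fold), chromosome 19 from 37740001 to 37770000 (band 19qC2) (14.1-fold against 3.79-fold) and chromosome 1 from 78020001 to 78070000 (band 1qC4) (6.08-fold against 1.88-fold). At these 4 blocks liver also lay above endoderm, at 4.04-, 17.8-, 18.8- and 5.95-fold. Lower values in pancreas were seen on chromosome 6 from 48400001 to 48430000 (band 6qB2.3), with 2.23-fold (95% interval 1.49 to 3.29) against 12.6-fold (95% interval 8.78 to 18.6) in endoderm. Nonendoderm (4.58-fold), liver (2.97-fold) and endocrine cells (5.14-fold) also lay under endoderm there, so the low value was not particular to pancreas. Input reads at this block numbered 39 in endoderm and 79 in pancreas, and H3K27me3 reads 130 and 41. Part of the high endoderm value thus came from its low input. On chromosome 7 from 70210001 to 70240000 (band 7qC), the values were 1.76-fold (95% interval 1.22 to 2.51) in pancreas and 6.65-fold (95% interval 5.03 to 8.85) in endoderm, while liver had 3.37-fold, nonendoderm 10.9-fold and endocrine cells 27.1-fold. On chromosome 7 from 143930001 to 143980000 (band 7qF5), pancreas lay at input level (0.965-fold) and endoderm at 4.75-fold. Nonendoderm (2.57-fold), liver (1.70-fold) and endocrine cells (1.94-fold) were under endoderm at this block too.

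There were 58 blocks higher in pancreas (1.97 Mb) and 67 lower (2.17 Mb), against at most 3 from counting noise. With background scaling the blocks numbered 28 higher and 116 lower, and with duplicate reads kept 153 higher and 114 lower, so the balance between directions depends on the processing. For single bins the numbers were 4904 and 5025 (2641 and 2832 from counting noise), and 3108 and 6461 with background scaling. Of the deposited regions, 397 were higher and 344 lower, against 149 and 149 from counting noise, or 682 and 189 with background scaling. The 5 single bins with the largest difference in favour of pancreas over endoderm began at 96890001 on chromosome 16, 78240001 on chromosome 16, 154270001 on chromosome 3, 72130001 on chromosome 1 and 23310001 on chromosome 12, with log2 differences of 3.12 to 3.90. The 5 on the opposite side began at 47870001 on chromosome 9, 48400001 on chromosome 6, 111060001 on chromosome 14, 108520001 on chromosome 3 and 48060001 on chromosome X, with log2 differences of -3.02 to -3.50. In 5 of the former and 3 of the latter, the library with fewer H3K27me3 reads held under 10.

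Within E10.5, pancreatic progenitors were compared with immature hepatocytes, the sister branch. H3K27me3 on chromosome 2 from 26360001 to 26400000 (band 2qA3) stood at 11.01-fold (95% interval 8.89 to 13.7) in pancreas and 1.87-fold (95% interval 1.24 to 2.77) in liver, and endoderm had 8.46-fold, so that liver differed from both. Nonendoderm (2.49-fold) and endocrine cells (3.96-fold) also lay under pancreas and endoderm there, so the low value was not particular to liver. Pancreas was also higher on chromosome 15 from 77900001 to 77940000 (band 15qE1) (5.36-fold against 1.55-fold). The largest difference lay on the liver side. The chromosome 2 domain from 147720001 to 147750000 had 1.63-fold (95% interval 1.12 to 2.34) in pancreas against 26.7-fold (95% interval 20.7 to 35.0) in liver. On chromosome 9 from 74630001 to 74660000 (band 9qD), pancreas had 3.01-fold (95% interval 2.20 to 4.10) and liver 22.8-fold (95% interval 18.0 to 29.2), with 8.11-fold in endoderm, 10.8-fold in nonendoderm and 8.00-fold in endocrine cells, making pancreas the lowest of the 5. On chromosome 12 from 58450001 to 58480000 (band 12qC1), pancreas had 3.27-fold (95% interval 2.41 to 4.41), liver 22.1-fold and endocrine cells 20.3-fold. Endoderm had 3.62-fold (95% interval 2.73 to 4.79) there, so pancreas and endoderm cannot be ranked beyond counting error. On chromosome 14 from 62190001 to 62230000 (band 14qD1), pancreas was again the lowest of the 5, at 2.97-fold, with 5.59-fold in endoderm, 16.96-fold in liver and 18.5-fold in endocrine cells.

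After quantile normalization this comparison had the fewest blocks, 33 higher in pancreas (1.1 Mb) and 29 lower (0.990 Mb), with at most 4 from counting noise. Background scaling changed the split to 14 and 72, and equal depth to 17 higher and 38 lower, both with more lower than higher. Single bins numbered 4352 higher and 4178 lower against 3178 and 2913 from counting noise, the closest of the 5 comparisons, and 3036 and 5242 with background scaling. The deposited regions gave 353 and 379 against 139 and 140, or 189 and 1197 with background scaling. Of these the first-ranked lower region lay on chromosome 12 from 58456484 to 58457971 (band 12qC1), inside the chromosome 12 block, with 1 read in pancreas and 29 in liver. The 5 single bins with the largest difference in favour of pancreas over liver began at 64960001 on chromosome X, 68490001 on chromosome X, 80250001 on chromosome X, 106720001 on chromosome 6 and 75480001 on chromosome 15, with log2 differences of 3.23 to 3.62. The 5 on the opposite side began at 30650001 on chromosome 11, 69470001 on chromosome 4, 147720001 on chromosome 2, 51650001 on chromosome 7 and 11310001 on chromosome 4, with log2 differences of -3.59 to -4.78. In 5 of the former and 5 of the latter, the library with fewer H3K27me3 reads held under 10.

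Endocrine progenitors against pancreatic progenitors addressed endocrine specification, the step the study was about. By the stage field these populations also differ in age, which cannot be separated from lineage here. Endocrine cells had less H3K27me3 than pancreas at several domains, and at some of them less than any other population. On chromosome 5 from 101880001 to 101910000 (band 5qE4), endocrine cells had 2.48-fold (95% interval 1.80 to 3.44) against 9.71-fold (95% interval 7.67 to 12.4) in pancreas, 8.88-fold in endoderm and 22.4-fold in liver, the lowest of the 5. On chromosome 10 from 80800001 to 80840000 (band 10qC1) the values were 4.66-fold in endocrine cells and 15.8-fold in pancreas, and on chromosome 15 from 85440001 to 85520000 (band 15qE2), an 80 kb block, 5.14-fold and 13.5-fold. On chromosome 2 from 178570001 to 178600000 (band 2qH4), the values were 2.50-fold and 7.74-fold. Liver had 2.75-fold, nonendoderm 3.31-fold and endoderm 5.08-fold there. Endocrine cells, liver and nonendoderm cannot be ranked beyond counting error on these folds. The block on chromosome 2 from 26350001 to 26400000 (band 2qA3), high in endoderm (7.64-fold) and pancreas (9.80-fold), stood at 3.39-fold in endocrine cells, with 2.37-fold in nonendoderm and 2.17-fold in liver.

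Among the deposited regions the steepest difference lay on chromosome 2 from 146877329 to 146881807 (band 2qG2), with 7 H3K27me3 reads in endocrine cells and 54 in pancreas, although the endocrine library was the deepest. Enrichment there was 1.72-fold (95% interval 0.546 to 5.20) in endocrine cells and 38.6-fold (95% interval 16.6 to 110) in pancreas, with 14.2-fold to 72.4-fold in the other three. The log2 difference after quantile normalization was -4.88 (95% interval -6.24 to -4.05). Next came chromosome 4 from 153481738 to 153488039 (band 4qE2), with 5.79-fold in endocrine cells against 35.6-fold in pancreas, and chromosome 11 from 118898178 to 118900432 (band 11qE2), with 4.19-fold against 33.6-fold. These regions were singled out after their values were seen.

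Higher endocrine values were found both at domains marked in other populations and at domains near input level in them. The block on chromosome 7 from 70200001 to 70250000 (band 7qC) had 25.2-fold (95% interval 20.8 to 30.8) in endocrine cells and 3.16-fold (95% interval 2.54 to 3.91) in pancreas, with 8.75-fold in nonendoderm. On chromosome 1 from 106750001 to 106780000 (band 1qE2.1), endocrine cells had 5.48-fold (95% interval 4.28 to 7.07), and the other populations had 0.778- to 1.05-fold. On chromosome 7 from 71080001 to 71110000 (band 7qC) the endocrine value was 4.02-fold against 0.518-fold in pancreas, and on chromosome 7 from 35700001 to 35730000 (band 7qB2) it was 11.2-fold against 1.43-fold.

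After quantile normalization 75 blocks (2.80 Mb) were higher in endocrine cells and 46 (1.56 Mb) lower, with at most 2 from counting noise. With background scaling alone the split was 759 higher and 9 lower, and that of single bins 18276 and 862 in place of 4358 and 3669 (2319 and 2071 from counting noise). With duplicate reads kept, blocks gave 160 higher and 71 lower, and single bins gave 8141 higher and 8518 lower. More blocks were higher than lower under every setting tried, but the size of the excess, and for single bins its direction, depended on the processing. The deposited regions gave 525 higher and 509 lower, or 2268 and 100 with background scaling. The 5 single bins with the largest difference in favour of endocrine cells over pancreas began at 70230001 on chromosome 7, 105200001 on chromosome 9, 82950001 on chromosome 7, 44340001 on chromosome 19 and 131980001 on chromosome 3, with log2 differences of 3.33 to 3.66. The 5 on the opposite side began at 146870001 on chromosome 2, 122790001 on chromosome 1, 116930001 on chromosome 12, 153480001 on chromosome 4 and 85470001 on chromosome 15, with log2 differences of -2.97 to -3.26. In 5 of the former and 2 of the latter, the library with fewer H3K27me3 reads held under 10.

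**Figure D3:**
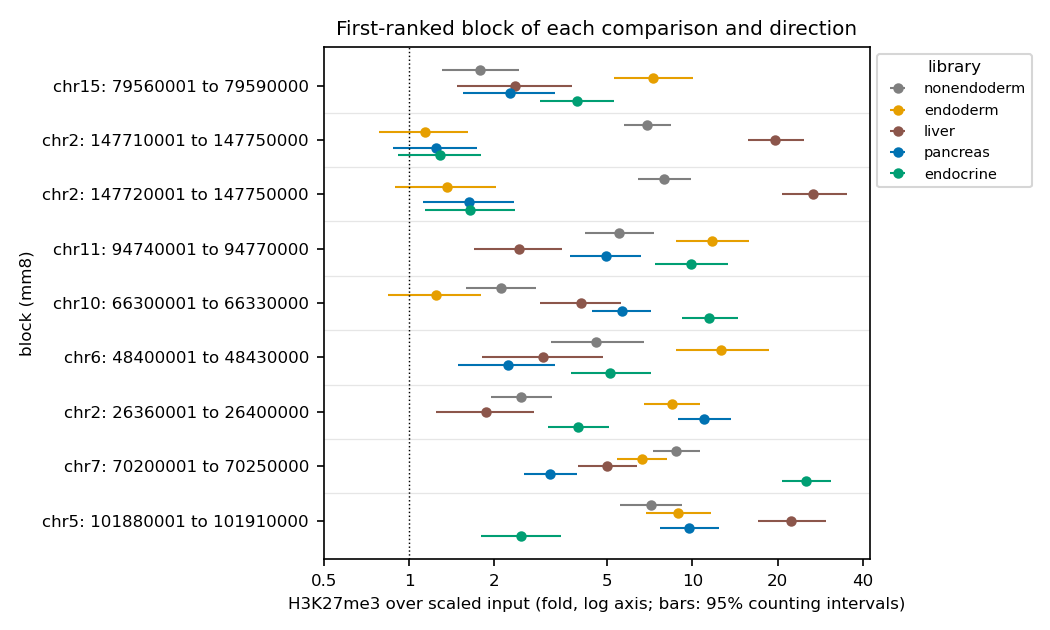
Enrichment of H3K27me3 over scaled input (x axis, fold, log axis) at the first-ranked block of each comparison and direction (y axis, mm8 positions), with 1 point per library, bars for 95% counting intervals and a dotted line at input level. The chromosome 5 block stands at 2.48-fold in endocrine cells and 9.71-fold in pancreas.

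**Figure D4:**
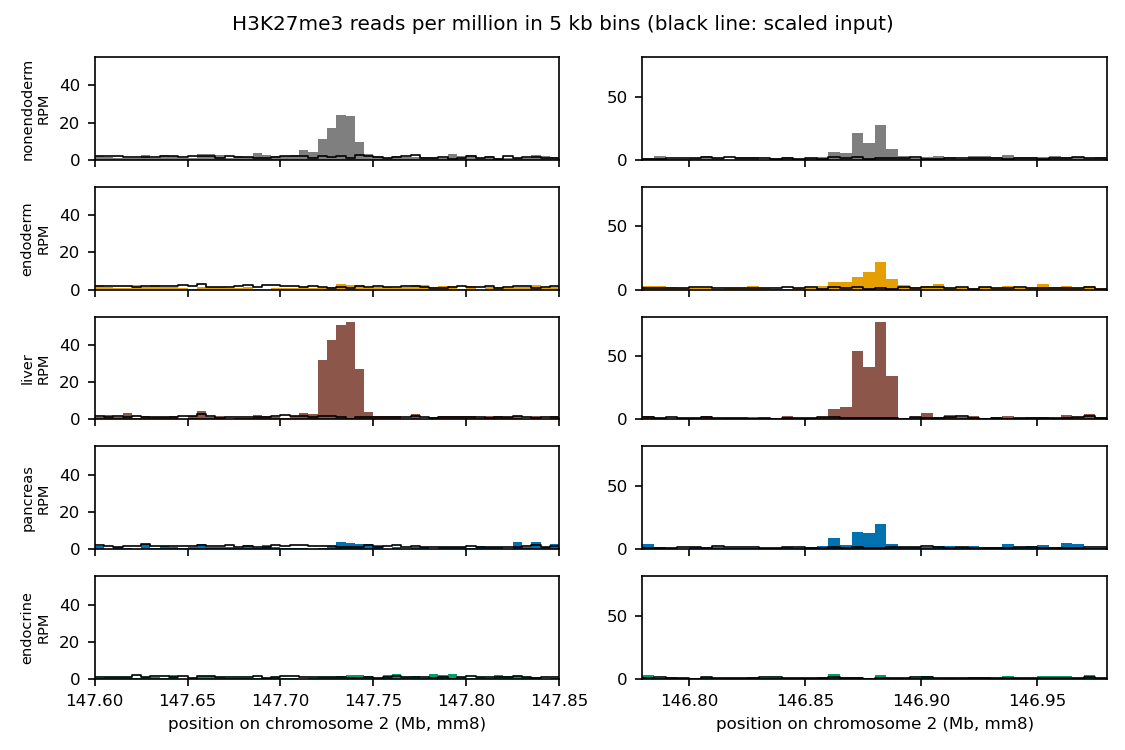
Distinct H3K27me3 reads (RPM, y axes) in 5 kb bins along 2 parts of chromosome 2 (x axes, Mb), with 1 row per population and the scaled input as a black line. The left domain is lower in endoderm, pancreas and endocrine cells than in nonendoderm and liver, and the right domain, which holds the region from 146877329 to 146881807, is lowest in endocrine cells.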

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

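The blocks and this search were chosen only after the result was seen. At 4 of the 615 differing blocks, H3K27me3 lay above input in 1 population and below it in the other, with counting intervals that exclude input level on both sides, and this opposite direction is why they are given here. On the same scale, autosomal bins that were not marked summed to 0.831-fold in endoderm, 0.808-fold in liver and 0.8002-fold in pancreas. The lower interval at 3 of the 4 blocks includes that level, and only the endoderm interval on chromosome 6 lies under it, so the other three lower values are not distinguishable from unmarked chromatin. The difference was not tested against replicates, and no explanation was weighed. On chromosome 6 from 137480001 to 137520000 (band 6qG1), enrichment was 3.42-fold (95% interval 2.36 to 4.95) in liver and 0.474-fold (95% interval 0.268 to 0.787) in endoderm. On chromosome 7 from 71080001 to 71110000 (band 7qC), it was 4.02-fold (95% interval 2.98 to 5.47) in endocrine cells and 0.518-fold (95% interval 0.275 to 0.904) in pancreas. The block on chromosome 8 from 36690001 to 36720000 (band 8qA4) had 2.43-fold (95% interval 1.63 to 3.57) in pancreas and 0.500-fold (95% interval 0.240 to 0.945) in liver, and the block on chromosome 6 from 42510001 to 42540000 (band 6qB2.1) had 0.444-fold (95% interval 0.205 to 0.859) in liver and 2.41-fold (95% interval 1.69 to 3.41) in endoderm.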

How the results depend on the processing

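The counts of blocks, and leaving out bins of high input, were chosen only after the result was seen. Without the filter on input reads, and without bins of high input, all 25 counts stayed within 1.5 times. Over all settings 125 of 203 recomputed values stayed within that limit, and 78 did not. The balance of higher and lower was not stable: it turned under at least 1 alternative for the blocks of every comparison but endocrine versus pancreas, and for the bins of all 5 comparisons. Where values moved or turned the cause was not tested, except that a lower threshold calls more by construction. Thinning to equal depth moved 4 of 25 counts, and depth limits what can be seen in single bins, where counting noise alone gave the numbers of calls stated for each comparison. The planned window of 1 kb around transcription starts and the planned gene lists were not run, for want of gene positions on mm8.

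With all reads as deposited, marked bins numbered 55898 in pancreas and endoderm versus nonendoderm gave 10266 bins higher and 11247 bins lower, 164 blocks higher and 168 blocks lower. Liver versus endoderm gave 11636 bins higher and 11730 bins lower, 183 blocks higher and 241 blocks lower and pancreas versus endoderm gave 10600 bins higher and 9903 bins lower, 153 blocks higher and 114 blocks lower. Pancreas versus liver gave 11281 bins higher and 10899 bins lower, 111 blocks higher and 76 blocks lower and endocrine versus pancreas gave 8141 bins higher and 8518 bins lower, 160 blocks higher and 71 blocks lower. With the 5 inputs pooled, marked bins numbered 21899 in nonendoderm, 22680 in endoderm, 19620 in liver, 19457 in pancreas, 33857 in endocrine and endoderm versus nonendoderm gave 1696 bins higher and 2290 bins lower, 24 blocks higher and 37 blocks lower. Liver versus endoderm gave 3241 bins higher and 3493 bins lower and pancreas versus endoderm gave 2333 bins higher and 2338 bins lower, 31 blocks higher and 40 blocks lower. Pancreas versus liver gave 2034 bins higher and 2156 bins lower, 22 blocks higher and 24 blocks lower and endocrine versus pancreas gave 1590 bins higher and 1296 bins lower, 49 blocks higher and 27 blocks lower. With background scaling only, endoderm versus nonendoderm gave 4705 bins higher and 4634 bins lower, 59 blocks higher and 30 blocks lower and liver versus endoderm gave 148 blocks higher and 146 blocks lower. Pancreas versus endoderm gave 3108 bins higher and 6461 bins lower, 28 blocks higher and 116 blocks lower and pancreas versus liver gave 3036 bins higher and 5242 bins lower, 14 blocks higher and 72 blocks lower. Endocrine versus pancreas gave 18276 bins higher and 862 bins lower, 759 blocks higher and 9 blocks lower. With scaling to the total read number, marked bins numbered 18779 in nonendoderm, 25070 in endoderm, 19817 in liver, 21193 in pancreas, 24357 in endocrine. At equal depth, endoderm versus nonendoderm gave 5366 bins higher and 4809 bins lower, 57 blocks higher and 30 blocks lower and liver versus endoderm gave 5797 bins higher and 5752 bins lower, 81 blocks higher and 75 blocks lower. Pancreas versus endoderm gave 34 blocks higher and 46 blocks lower and pancreas versus liver gave 4089 bins higher and 4372 bins lower, 17 blocks higher and 38 blocks lower. With a pseudocount of 1 RPM, endoderm versus nonendoderm gave 28 blocks higher and 46 blocks lower and pancreas versus endoderm gave 3867 bins higher and 3809 bins lower. Endocrine versus pancreas gave 2822 bins higher and 2621 bins lower. With a threshold of 1.5-fold, marked bins numbered 78850 in nonendoderm, 94807 in endocrine and endoderm versus nonendoderm gave 7534 bins higher and 7937 bins lower, 67 blocks higher and 82 blocks lower. Pancreas versus endoderm gave 7498 bins higher and 7736 bins lower, 83 blocks higher and 103 blocks lower and pancreas versus liver gave 6463 bins higher and 6440 bins lower, 43 blocks higher and 43 blocks lower. Endocrine versus pancreas gave 8646 bins higher and 6159 bins lower, 158 blocks higher and 61 blocks lower. With no filter on input reads, pancreas versus liver gave 30 blocks higher and 30 blocks lower. The share of listed regions found on all 3 lists was 61.2% for regions of 2 kb or wider and 26.96% for the higher scores, against 44.1%. A larger minimum overlap changed nothing, since shared regions had identical coordinates.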

Other observations

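The tests below on the liver library, on the swap of libraries, on nearness to the other populations and on the intervals of the densest windows were chosen only after the result was seen. In all 5 populations, more bins were marked in G-light bands than in the darkest. In G-light (gneg) bands 17.004% of bins were marked in pancreas and 28.8% in endocrine cells, against 8.63% and 17.002% in the darkest bands (gpos100). Of 615 differing blocks, 51.4% lay in G-light bands, close to the share of marked bins there (49.7% in endocrine cells to 52.3% in endoderm). On the X chromosome, 13.1% of bins were marked in nonendoderm and 23.6% in endocrine cells, against 16.6% and 24.4% of autosomal bins. Around the centres of the 3851 regions on all 3 lists, the excess over input 10 kb to the right was 31.3% of that at the centre in nonendoderm, 26.7% in endoderm, 23.8% in liver, 25.9% in pancreas and 26.2% in endocrine cells.

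At the 54 blocks lower in endoderm, liver lay nearer to nonendoderm in 39, pancreas in 27 and endocrine cells in 22, and at the 43 blocks higher in endoderm the numbers were 32, 22 and 22, although the same endoderm and nonendoderm reads chose the blocks, so only the contrast between populations can be read. A candidate explanation is that the liver sort held cells like those of the nonendoderm library. The prediction written for it, liver values at or under those of nonendoderm, follows only if hepatocytes without such cells lie no higher there. That level is not known, so the test cannot decide this explanation. At 20 blocks called with one part of the nonendoderm reads and measured with the rest, liver lay above nonendoderm in 10. The median difference was -0.0303 (log2, 95% bootstrap interval -0.41 to 0.24), and the explanation stays open. A first version on all reads (-0.37 over 54 blocks) was set aside because its blocks were selected for high nonendoderm values. A swap of the liver and nonendoderm libraries could not be told apart either, since their correlations with pancreas differed by -0.00809, and a true property of immature hepatocytes stays open as untested.

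With background scaling alone, 18276 bins were higher in endocrine cells than in pancreas and 862 lower, a ratio of 21.2. At equal depth the numbers were 8939 and 2860, a ratio of 3.13, between the bounds set beforehand for depth as the cause and for its exclusion, so deeper sequencing may account for part of the imbalance and cannot be told apart from other causes of the rest. A higher yield of the endocrine immunoprecipitation would leave unmarked chromatin at input level. In the 117807 bins where the other 4 populations together lay at or below input, endocrine cells had 0.855-fold (95% interval 0.853 to 0.857), within the bound set beforehand, but 73.2% of these bins also set the endocrine scale, so the outcome was largely built in and the test, first read as favouring yield, decides nothing. Yield and a real increase of the mark in endocrine cells cannot be told apart with 1 library per population.

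The hypothesis that the densest H3K27me3 marks the 4 Hox gene clusters, which lie on mouse chromosomes 2, 6, 11 and 15, was tested by chromosome alone. Of the 4 windows of 100 kb with the highest mean enrichment, at least 1 Mb apart, 3 lay on those chromosomes, between the bounds set beforehand (4 for the hypothesis, 2 or fewer against it): chromosome 15 from 102740001, chromosome 11 from 96060001 and chromosome 2 from 74450001. The window ranked first lay on chromosome 8 from 126420001 to 126520000 (band 8qE2), at 24.5-fold in nonendoderm and 115-fold in endocrine cells, and the fifth lay on chromosome 6 from 52110001. The 95% intervals of the chromosome 8 window lay above those of the densest window on the named chromosomes in all 5 populations, which excludes only the strict reading, that the 4 Hox clusters are denser than every window off these chromosomes, and restates the observed first rank of that window. No gene was placed on these positions, and no biological explanation of the chromosome 8 window was tested.

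Reads on the plus strand made up 41.2% to 44.1% of the 10 libraries, inputs included. Among distinct input reads, 100% of 2573 windows of 1 Mb had a plus-strand share under 50%, with a median of 45.1%. Mitochondrial reads were 0.0787% to 0.131% of distinct input reads and 0.00441% to 0.00967% of distinct H3K27me3 reads.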
